A study of Mus musculus with 14 samples.

How the data were processed

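Total RNA from 3T3-L1 cells, a mouse fibroblast line that turns into fat cells under hormone treatment, was hybridised to 14 expression arrays, 1 per sample. Per the labels' protocols, cells carried lentivirus with either a scrambled sequence or a sequence against TP53INP2, RNA was isolated with Trizol and a column kit, amplified with the Ovation system and labelled with biotin. Samples were grouped by the genotype, time and replicate number in the labels: control and knockdown cells at day 0, with 3 arrays each, and at day 7 of differentiation, with 4 arrays each. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Control and knockdown cells differ in the virus they carry. A lasting difference between these cells, from the virus or from how they were derived, cannot be told apart from an effect of the knockdown. Changes with knockdown below are differences between these groups.

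The deposited values are log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA (background correction, quantile normalization and summarisation of probes) and the affy package; their versions are not given in the sources used here. The log base was taken from the range of the values, which ran from 1.13 to 14.37. The table held 45101 probe sets and no missing value, and the median of an array lay between 5.44 and 5.57. RMA compresses changes of dim genes, so a fold change from or to a level near the bottom of the scale is understated. The files give no detection call, so no gene was called absent, and the number of arrays limits the precision.

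Of the 45101 probe sets, 64 were control probe sets and were left out of the tests. The platform annotation gave 1 gene symbol for 34945 of the others and several for 932, while 9160 are unnamed here. Symbols were checked by gene ID against a RefSeq gene table of assembly GRCm38.p6, used only for names: 18032 of the 18193 genes were found in it and 0 symbols needed an update. Where a gene had more than 1 probe set (9010 genes), the probe set with the highest mean over the 14 arrays stood for it. The array files carry no genome coordinates, and none are given.

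All 14 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12.6 degrees of freedom after moderation). The 5 contrasts were knockdown minus control at day 0, the same at day 7, the difference between these effects, and day 7 minus day 0 in control and in knockdown cells. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 18193 genes. Every adjusted p of a gene below comes from this limma fit, and errors of log2 fold changes are its standard errors (SE). On simulated data with the real genes' means and spread, the day 0 contrast recovered 12% of genes changed by 0.5 on the log2 scale and 66% of those changed by 1, with 5 false calls among 83. The day 7 contrast recovered 29% and 86%, with 3 false calls among 118. These shares and false calls describe the simulated data only. Real arrays of the same replicate number deviated together, and some arrays of a group lay close together, as given below. The simulation therefore cannot show how many of the real calls are false.

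Before the data were examined, 28 gene lists were fixed, on fat cell biology, Wnt signalling, autophagy and lysosomes, the cell cycle, matrix, stress and immune responses, and markers of other cell types. Of 537 listed entries 501 matched a measured gene; the others are unnamed here or were not analysed here. Each list was tested in each contrast with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 140 tests. Camera called 43 of these tests, and 0 of them held with an estimated correlation. With that correlation 0 of all 140 tests passed. This includes differentiation of control cells, where all 27 genes of S phase and mitosis rose singly (camera adjusted p = 0.55). A call lost with an estimated correlation therefore does not show that the list is unchanged. A list is named as called below by camera. Fry, a rotation test of each list on its own, was also run with the same adjustment. At day 0 it called none of camera's lists (adjusted p from 0.136 to 0.483). It called the thyroid hormone response (0.00751), brown and beige (0.0118) and unfolded protein lists (0.0238) there. At day 7 it called the matrix (0.0118), fatty acid oxidation (0.0176) and thyroid hormone response lists (0.0454). For the difference between days fry called none of camera's lists (adjusted p from 0.0963 to 0.301). It called the brown and beige (0.0252) and unfolded protein lists (0.0454) instead. In differentiation of control cells fry also called the lists reported below (adjusted p from 5.52e-05 to 0.0291). Wnt pathway components (0.000563) and ESCRT genes (0.000215) were called there by fry but not by camera. In 31 tests, 0 of them called, the list's median, mean and test differed in sign. Members are counted over all genes and also adjusted over the list alone.

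The genes named were set by a rule fixed beforehand. They are Trp53inp2 and the 10 raised and 10 lowered genes with the largest change among called genes whose groups did not overlap, for knockdown at each day and for differentiation in control cells. For the other contrasts 5 in each direction were taken. Added to these are up to 4 called members of each list for the knockdown contrasts, or the member with the largest change where none was called. Where fewer than 5 genes passed in a direction, those with the smallest p were given as values. Provisional gene symbols were passed over.

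Arrays with the same replicate number and day deviated together from their group means. Over the brighter genes, the correlations of these deviations were 0.27, 0.23 and 0.32 at day 0 and 0.52, 0.59, 0.74 and 0.25 at day 7. The numbers were therefore taken to pair the samples in the comparisons by pair. The main fit leaves this pairing out, and so do its counts, named genes and list calls. The pairing comes from the replicate numbers in the labels and this check. At day 7 the check does not tell replicates 1 and 2 apart. Control replicate 1 with knockdown replicate 2 had 0.55, and control replicate 2 with knockdown replicate 1 had 0.61. A fit with the replicate number within a day as a block is given where it ends the call of a named gene or changes that of a list. It called 844 genes at day 0, 2680 at day 7 and 196 for the difference between days. The main fit called 328, 1197 and 4. Further alternatives were other scalings, other rules for probe sets, a filter on dim genes, other variance models, array weights and leaving out each array. 4 were added after the data were seen: averaging replicates 1 and 2, leaving out both day 7 replicate 3 arrays, a covariate for RNA quality, and the gene lists with the block and an estimated correlation.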

Results

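The data are genome-wide expression values of 3T3-L1 preadipocytes, control or depleted of TP53INP2, before differentiation (day 0, 2 days after confluence) and after 7 days in differentiation medium. TP53INP2 is a protein known to take part in autophagosome formation and to act as a coactivator of thyroid hormone receptors. The design asks which genes respond to its loss in preadipocytes, which respond in differentiated cells, and whether the differentiation programme differs. Day 0 groups had 3 arrays and day 7 groups had 4. Quartiles of the arrays were alike, with medians between 5.44 and 5.57 on the log2 scale.

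The first principal component held 56.4% of the variance and parted day 0 from day 7. Day 0 arrays lay between -53.2 and -48.1 on it. Day 7 controls lay at 38.4, 38.7, 12 and 11.7, and day 7 knockdown arrays at 60.3, 60.1, 31.4 and 54.3, higher than the control of the same number in 4 of 4 pairs. Replicates 1 and 2 lay closer together than other arrays of a group: the SD of their difference over the brighter genes was 0.111 in day 7 controls and 0.179 in day 7 knockdown cells. These compare with 0.397 to 0.526 and 0.307 to 0.52 when either was set against replicates 3 and 4. At day 0 it was 0.246 in controls and 0.224 in knockdown cells, and 0.323 to 0.425 against replicate 3. They were not identical and were counted as separate samples in every main fit, though at day 7 they may lie too close together for that. If they are repeats of 1 sample, the errors and p-values may be too small and the counts too high. Averaging them, which leaves fewer samples, took the count from 328 to 24 genes at day 0 and from 1197 to 64 at day 7. The counts after averaging are given beside each comparison.

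**Figure D1:**
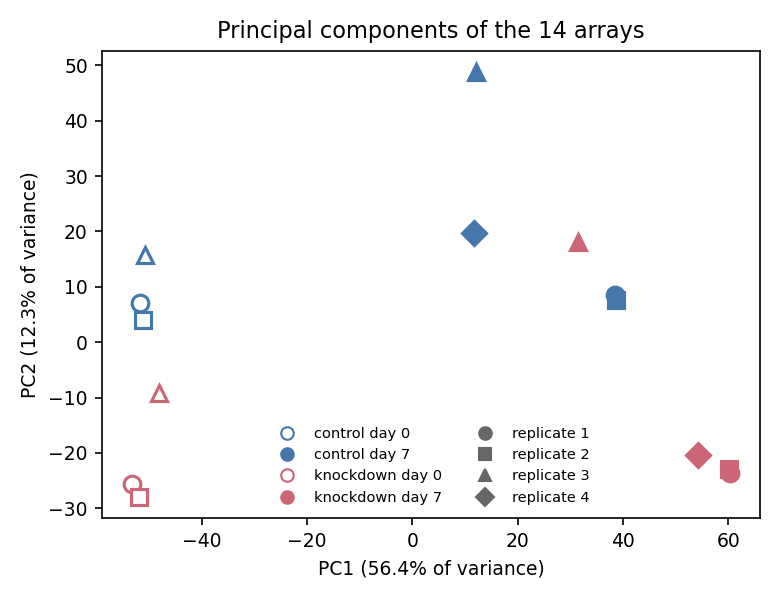
Each array's position on the first (x axis) and second (y axis) principal component of the 14 arrays, in arbitrary units; open symbols are day 0, filled symbols day 7, and shapes give the replicate number. Day 0 arrays lie between -53.2 and -48.1 on the first component, and the day 7 control arrays of replicates 3 and 4, at 12 and 11.7, lie nearest to them among the day 7 arrays.

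Trp53inp2 itself was lower in every knockdown array than in every control array of the same day. Its brighter probe set averaged 12.45 ± 0.07 (SD, n = 3) in day 0 controls and 11.28 ± 0.33 (SD, n = 3) in day 0 knockdown cells. The log2 fold change was -1.17 ± 0.15, which leaves 44.4% of the control level (95% confidence interval from the fit of all probe sets 35.3% to 55.9%; adjusted p = 0.00205). At day 7 it averaged 11.75 ± 0.03 (SD, n = 4) in controls and 10.18 ± 0.20 (SD, n = 4) in knockdown cells. The log2 fold change of -1.57 ± 0.13 leaves 33.7% (interval 27.6% to 41.2%; adjusted p = 0.000111). The decreases at the 2 days differed by -0.40 ± 0.20 (adjusted p = 0.421). Trp53inp2 also fell during differentiation, by 0.71 on the log2 scale in control cells (adjusted p = 0.00304). A second, dim probe set showed no decrease (0.20 ± 0.22 at day 0 and 0.24 ± 0.19 at day 7, adjusted p = 0.728 and 0.569 over all probe sets). The day 0 call was lost with the mean over both probe sets (-0.48, adjusted p = 0.105) and with replicates 1 and 2 averaged (-1.06, adjusted p = 0.165).

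**Figure D2:**
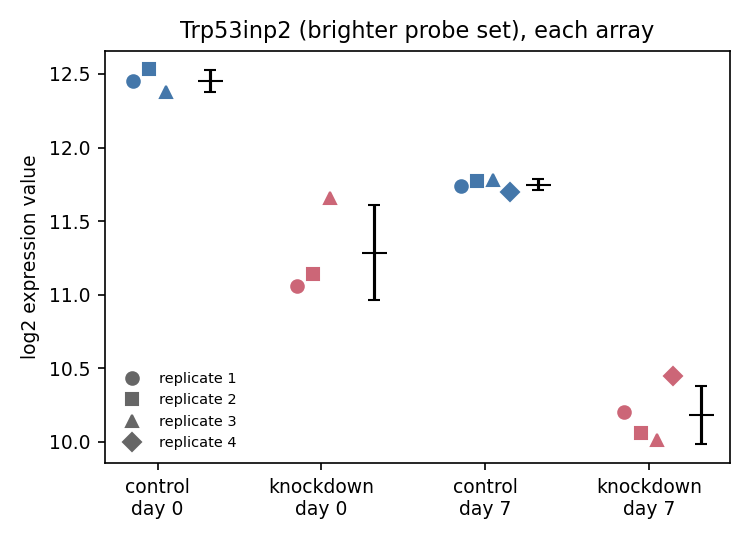
The log2 expression value (y axis) of the brighter Trp53inp2 probe set on each array, by group; shapes give the replicate number and black bars the mean and SD. Controls average 12.45 at day 0 and 11.75 at day 7, and knockdown cells 11.28 and 10.18.

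In preadipocytes at day 0, knockdown changed 328 genes, and most of them fell: 85 were higher and 243 lower, 35 and 111 of them by at least 2-fold. The largest decreases were in the homeobox gene Meox2 (-4.59 ± 0.51), the potassium channel gene Kcnc2 (-4.40 ± 0.40), the secreted matrix protein gene Adamtsl1 (-4.21 ± 0.47), Klhl4 (-4.19 ± 0.35) and Itm2a (-4.10 ± 0.43), with adjusted p between 0.000157 and 0.000861. Klhl4 went from 7.28 ± 0.05 in controls to 3.08 ± 0.33 in knockdown cells (SD, n = 3 each), near the bottom of the scale. Angptl7 (-3.29), the integrin gene Itga8 (-3.24), Pi15 (-3.20), the interleukin 7 receptor gene Il7r (-3.08) and the retinoic acid binding protein gene Crabp1 (-3.04) followed. The largest increases were in Wfdc17 (4.13 ± 0.78), Elfn1 (2.95 ± 0.60), the chemokine gene Ccl6 (2.95 ± 0.62), Vstm2a (2.71 ± 0.26) and the heparan sulfate sulfotransferase gene Hs3st3b1 (2.68 ± 0.34). Popdc3 (2.26), the bicarbonate cotransporter gene Slc4a4 (2.23), Epb41l4b (2.17), Spsb4 (2.12) and Parm1 (2.01) also rose; with the replicate block, Popdc3 had adjusted p = 0.0627. Of the 14 of these genes with several probe sets, Trp53inp2 included, 9 had another, dimmer one with under 50% of the printed change, such as Klhl4 (-0.57) and Hs3st3b1 (0.15 to 0.28), and in 8 another passed. A dim probe set of Slc4a4 had the opposite sign (-0.30).

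Pde3b, the phosphodiesterase through which insulin restrains lipolysis, fell by 2.68 on the log2 scale (adjusted p = 0.000306), and Dio2, which makes active thyroid hormone, by 2.40 (adjusted p = 0.00129). The endocrine factor gene Fgf21 had -0.75 ± 0.16 (adjusted p = 0.0355, and 0.0584 with the replicate block). Of 11 thyroid hormone response genes, 2 fell (Dio2 and Fgf21), 0 rose and 9 did not pass, with 3 lower when adjusted over the list alone and 1 with the replicate block; the list was not called (adjusted p = 0.184). Among 24 Wnt and beta-catenin target genes, 1 fell, the receptor gene Bambi (-1.36 ± 0.18, adjusted p = 0.00205), and 23 did not pass, with the same count adjusted over the list alone. Among 22 Wnt pathway components 0 passed by either adjustment, and 1 was higher with the replicate block; the largest value was 0.87 ± 0.53 for the Wnt antagonist gene Sfrp2 (adjusted p = 0.482). Of 33 genes of the autophagy machinery, 1 rose, the phosphoinositide-binding protein gene Wipi2 (0.58 ± 0.12, adjusted p = 0.0355; the same count over the list alone), and the list was not called (adjusted p = 0.351). By the probe set of largest interquartile range Wipi2 had -0.155 (adjusted p = 0.687). Of 18 adipogenic transcription factor genes 1 rose, Klf5 (1.11 ± 0.23, adjusted p = 0.0344), and 1 rose and 1 fell both over the list alone and with the replicate block. The list had adjusted p = 0.0845, and 0.0336 with the replicate block (adjusted p = 0.853 with an estimated correlation).

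Camera called 4 lists at day 0, and for each of them 0 to 1 members passed singly. The 24 mature adipocyte markers, genes of lipid storage and adipokines, were shifted up by a median of 0.36 (adjusted p = 0.00103; 0 members passed by either adjustment, 1 with the replicate block). That call was lost, at adjusted p = 0.718 with an estimated correlation. The median was 0.17 without day 0 knockdown replicate 2 and 0.55 without replicate 3. The 27 genes of S phase and mitosis were shifted down by a median of -0.51 (adjusted p = 2.1e-05; adjusted p = 0.718 with an estimated correlation), with 0 members past the threshold by either adjustment and 3 lower with the replicate block. This shift was not shared by the pairs: the list mean differed by -0.84 and -0.83 in replicates 1 and 2 and by 0.14 in replicate 3, and the median was -0.79 without day 0 knockdown replicate 3. The 17 contractile genes and targets of SRF or YAP had a median of -0.39 (adjusted p = 0.00893; adjusted p = 0.718 with an estimated correlation). Of these, 1 fell, the myosin light chain gene Myl9 (-1.95 ± 0.40, adjusted p = 0.0311), with 4 lower over the list alone and 4 with the replicate block. The contractile call was lost without the dimmest 40% of genes (median -0.33, adjusted p = 0.0524). The 24 interferon response genes had a median of -0.69 (adjusted p = 0.0105; adjusted p = 0.891 with an estimated correlation), and the list mean was lower in knockdown cells in 3 of 3 pairs. Of these genes 0 passed by either adjustment and 8 fell with the replicate block; Rsad2, an antiviral enzyme gene, had -1.83 ± 0.90 (adjusted p = 0.362). The interferon call was lost without day 0 control replicate 3 and without day 0 knockdown replicate 1 or 2, with medians of -0.61, -0.52 and -0.65 and adjusted p up to 0.129. It was also lost with all arrays shifted to 1 median, where the list's median was -0.76 (adjusted p = 0.0857). With the replicate block, the 18 fatty acid oxidation genes were also called, shifted up (adjusted p = 0.0185, against 0.0582 without it; adjusted p = 0.853 with an estimated correlation), with 2 members higher. Of the matrix genes 1 was lower then and of the cholesterol synthesis genes 1 higher, where 0 passed without the block.

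A measure of RNA quality moved with the day 0 groups in 2 of 3 control genes. The difference between the beta-actin control probe sets at the 3' and 5' ends was 3.54 ± 0.22 in controls and 2.98 ± 0.25 in knockdown cells (log2, SD, n = 3 each), with no overlap. The exact two-sided permutation p = 0.1 is the smallest that 3 against 3 allow (0.3 after Benjamini-Hochberg adjustment over 6 such tests). For Gapdh it was 2.18 ± 0.22 and 1.77 ± 0.16, with the same exact p. For the transferrin receptor it was 3.08 ± 0.10 and 2.73 ± 1.28 (exact permutation p = 0.7), with knockdown arrays on both sides of the controls. With the beta-actin difference as a covariate, added after the data were seen, the day 0 medians were 1.38 for mature adipocyte markers, -1.92 for interferon response genes and -0.70 for contractile genes. The day 0 count moved with single arrays: it was 104, 160 and 180 without control replicate 1, 2 or 3 and 113, 101 and 631 without knockdown replicate 1, 2 or 3. With the replicate block it was 844 (225 higher, 619 lower; 302 shared), with replicates 1 and 2 averaged 24 (5 higher, 19 lower), and with arrays shifted to 1 median 513 (74 higher, 439 lower). The balance turned with every probe set tested (1260, 791 higher and 469 lower) and was nearly even with the probe set of largest interquartile range (206 higher, 215 lower). Of the 28 called genes that the naming rule gave for day 0, Trp53inp2 not counted, 10 kept their call with replicates 1 and 2 averaged. Among them were Klhl4, Kcnc2, Itm2a, Il7r, Pde3b, Vstm2a and Parm1.

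After 7 days of differentiation, knockdown changed 1197 genes, 547 higher and 650 lower, 106 and 139 of them by at least 2-fold. The largest increases were in Popdc3 (3.00 ± 0.43), the helix-loop-helix regulator gene Id4 (2.74 ± 0.33), the ubiquitin ligase gene Rnf128 (2.61 ± 0.55), Aqp7, the glycerol channel of fat cells (2.56 ± 0.49), and the adhesion receptor gene Adgrg1 (2.38 ± 0.25), with adjusted p between 0.000477 and 0.0184. Rassf3 (2.33), Pdzd2 (2.32), the apolipoprotein gene Apoc3 (2.29), Aldh3b2 (2.26) and Trim29 (2.25) also rose. The largest decreases were in Klhl4 (-3.58 ± 0.30), Meox2 (-3.27 ± 0.44), Il7r (-3.22 ± 0.38), Slc22a22 (-2.82 ± 0.48) and the noradrenaline transporter gene Slc6a2 (-2.81 ± 0.52), with adjusted p between 0.000111 and 0.0101. Itm2a (-2.73), Tnfsf11, which encodes the cytokine RANKL (-2.71), the metalloproteinase inhibitor gene Timp3 (-2.68), Kcnc2 (-2.64) and the potassium channel gene Kcnj15 (-2.63) also fell. Other, dimmer probe sets of these genes often moved less. Of the 15 genes with several probe sets at day 7, Trp53inp2 included, 12 had another with under 50% of the printed change, and in 9 another passed. Those of Kcnj15, Pdzd2, Rassf3, Slc6a2 and Tnfsf11 included 1 with a change of the opposite sign, none of them larger than 0.13 on the log2 scale.

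**Figure D3:**
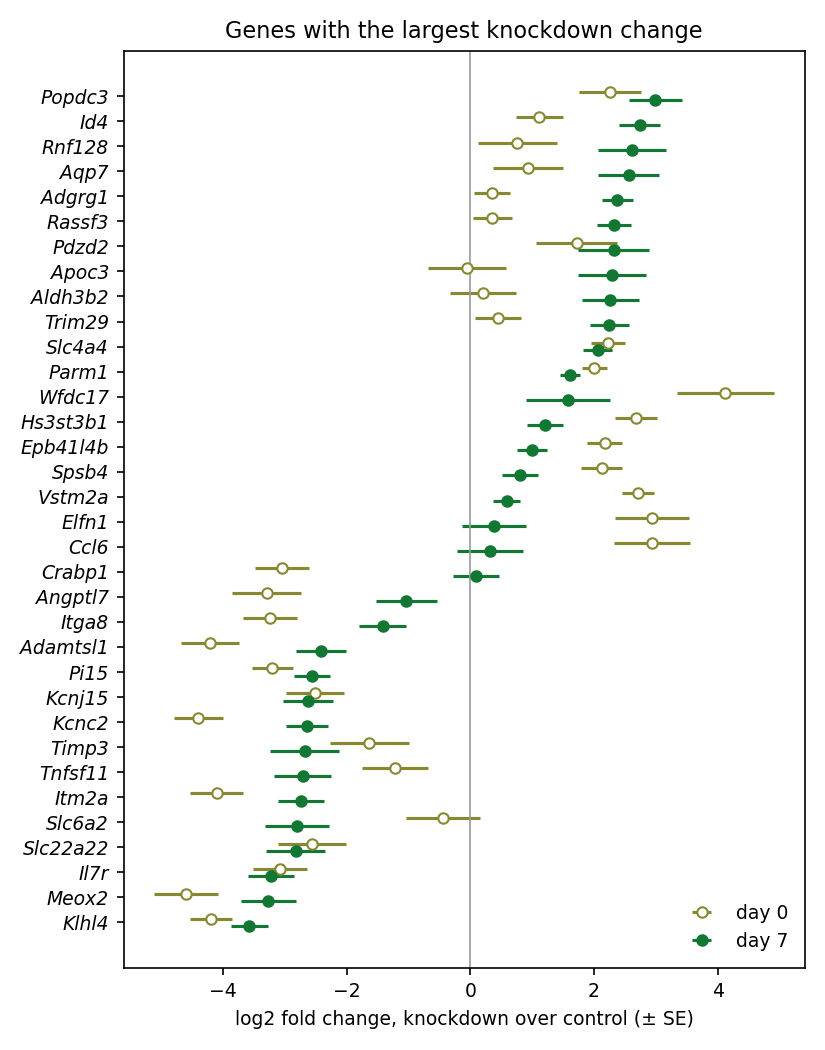
Log2 fold change of knockdown over control (x axis, with SE) at day 0 (open) and day 7 (filled) for the genes with the largest changes at either day, sorted by the day 7 value. Klhl4, Meox2 and Il7r are low at both days (-4.19, -4.59 and -3.08 at day 0), while Crabp1 is at -3.04 at day 0 and 0.10 at day 7.

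At day 7 camera called 10 lists, 6 shifted up and 4 shifted down in knockdown cells, while few of their members passed singly. The 24 mature adipocyte markers had a median of 0.78 (adjusted p = 4.22e-06; adjusted p = 0.687 with an estimated correlation), and 22 of the 24 values were above 0. Over all genes 2 rose, Aqp7 and Dgat2, the last enzyme of triglyceride synthesis (2.01 ± 0.41, adjusted p = 0.0162), 0 fell and 22 did not pass. Of the 24, 11 rose adjusted over the list alone, and 10 with the replicate block. The list mean was higher in knockdown cells in 4 of 4 pairs, by 0.59, 0.46, 0.86 and 1.82. Of 20 genes of fatty acid and triglyceride synthesis, 1 rose (Dgat2), 1 fell (the elongase gene Elovl5, -0.43 ± 0.08, adjusted p = 0.008) and 18 did not pass, with 10 higher and 1 lower over the list alone and 9 and 1 with the replicate block. That list had a median of 0.36 (adjusted p = 0.000196; adjusted p = 0.704 with an estimated correlation). Of 14 lipolysis and lipid droplet genes 1 rose (Aqp7) and 1 fell (Pde3b, -1.10 ± 0.22, adjusted p = 0.0134), with 5 and 2 over the list alone. The list had adjusted p = 0.0679, and 0.0129 with the replicate block (6 higher, 1 lower; adjusted p = 0.853 with an estimated correlation). Of the 18 adipogenic transcription factor genes 1 fell, Cebpd (-0.90 ± 0.19, adjusted p = 0.0173), and 0 rose, with the same counts over the list alone. With the replicate block 5 of them were higher and 2 lower.

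The lists of fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis and the cell cycle were also called as shifted up, and most of their members did not pass. Of 18 fatty acid oxidation genes 5 rose, among them Ehhadh, a peroxisomal enzyme of fatty acid oxidation (2.23 ± 0.14, adjusted p = 2.07e-05), Acads (0.83 ± 0.17), Hadha (0.58 ± 0.15) and Etfb (0.54 ± 0.14). Of the others 0 fell and 13 did not pass, with 7 higher and 1 lower over the list alone and 8 and 1 with the replicate block. The list's median was 0.31 (adjusted p = 0.000226; adjusted p = 0.687 with an estimated correlation). Of 21 oxidative phosphorylation genes 1 rose, the complex III gene Uqcrfs1 (0.73 ± 0.20, adjusted p = 0.0474), with 11 higher over the list alone and 7 with the replicate block. All 21 values were above 0, with a median of 0.26 (adjusted p = 5.8e-07; adjusted p = 0.687 with an estimated correlation). Of 17 cholesterol synthesis genes 1 rose, Cyp51 (1.53 ± 0.35, adjusted p = 0.026), with 2 over the list alone and 8 with the replicate block. The median was 0.34 (adjusted p = 0.000381; adjusted p = 0.772 with an estimated correlation). The 27 genes of S phase and mitosis had a median of 0.18 (adjusted p = 0.0433; adjusted p = 0.911 with an estimated correlation), with 0 members past the threshold by either adjustment and 2 higher with the replicate block. Without control replicate 3 the cholesterol synthesis median was 0.18, and without knockdown replicate 3 it was 0.58. The cell cycle call was lost under quantile normalization (median 0.17, adjusted p = 0.0692), without dim genes (0.18, adjusted p = 0.12), without both replicate 3 arrays (0.105, adjusted p = 0.154) and with the beta-actin covariate (0.097, adjusted p = 0.28). It was also lost without control replicate 3 or 4 (medians 0.13 and 0.04) and without knockdown replicate 1, 2 or 3 (medians 0.09, 0.12 and 0.14), with adjusted p up to 0.255.

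The lists of matrix, contractile, lysosomal and interferon response genes were called as shifted down, with 4, 2, 1 and 0 members past the threshold. Of 24 extracellular matrix genes 4 fell, the proteoglycan gene Dcn (-1.43 ± 0.32, adjusted p = 0.0233), the fibronectin gene Fn1 (-0.69 ± 0.14), Col3a1 (-0.35 ± 0.07) and Mmp2 (-0.34 ± 0.08). Of the others 0 rose and 20 did not pass, with 8 lower over the list alone and 9 with the replicate block. The median was -0.30 (adjusted p = 9.23e-07; adjusted p = 0.611 with an estimated correlation). Of 17 contractile genes and SRF or YAP targets 2 fell by either adjustment, Tgfb1i1 (-0.70 ± 0.12, adjusted p = 0.00808) and Tpm2 (-0.44 ± 0.11, adjusted p = 0.0387), and 7 were lower with the replicate block. That list's median was -0.27 (adjusted p = 0.00607; adjusted p = 0.707 with an estimated correlation), and its call was lost without control replicate 3 or knockdown replicate 4, with adjusted p up to 0.111. The contractile median was -0.07 and -0.18 then, -0.42 without control replicate 4, -0.55 without knockdown replicate 3 and -0.50 with the beta-actin covariate. Of 22 lysosomal genes 1 fell, the acid glucosidase gene Gaa (-0.78 ± 0.11, adjusted p = 0.00181), with 4 lower over the list alone and 3 with the replicate block. The lysosome list's median was -0.11 (adjusted p = 0.0288; adjusted p = 0.718 with an estimated correlation), lost without control replicate 4 or knockdown replicate 1 or 4, with medians of -0.10, -0.10 and -0.07 and adjusted p up to 0.145. It was -0.16 without knockdown replicate 3. The 24 interferon response genes had a median of -0.77 (adjusted p = 0.000628; adjusted p = 0.826 with an estimated correlation), lost without control replicate 3 at 0.105 (median -0.41); with the beta-actin covariate the median was -1.19. Of these 0 passed by either adjustment and 17 fell with the replicate block; the list mean was lower in knockdown cells in 4 of 4 pairs, and Mx1 had -1.71 ± 0.64 (adjusted p = 0.13).

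**Figure D4:**
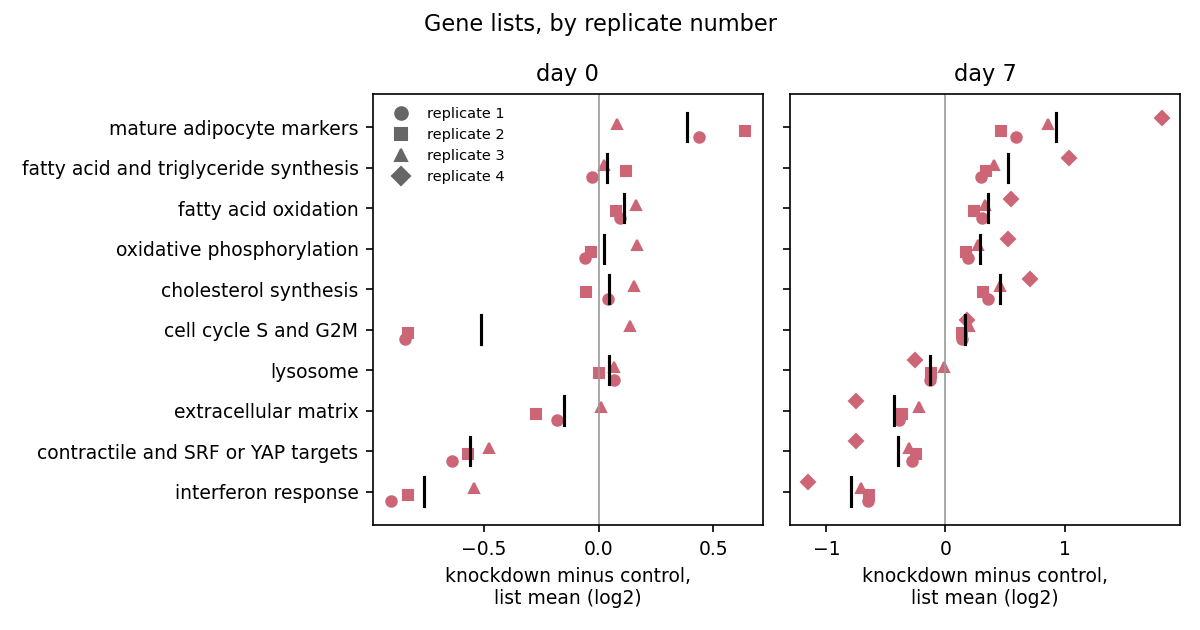
Difference of the list mean between the knockdown and control arrays of the same replicate number (x axis, log2) for 10 gene lists at day 0 and day 7; shapes give the replicate number and black bars the mean of the pairs. The mature adipocyte markers lie above 0 in 4 of 4 pairs at day 7, and the cell cycle list at day 0 lies at -0.84, -0.83 and 0.14.

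A few autophagy and ESCRT genes changed in each direction at day 7, when 1197 of all 18193 genes passed. Camera tests a shift in 1 direction and so does not test such changes. Fry without regard to direction gave unadjusted p = 6.38e-08 for autophagy and 1.36e-06 for ESCRT genes, with every array counted as a sample. It also gave 2.45e-08 for the brown and beige list, of which 1 gene rose and 1 fell. Of 33 autophagy genes 2 rose and 4 fell. Wipi2 rose (0.51 ± 0.11, adjusted p = 0.0197), and among those that fell were the conjugating enzyme gene Atg10 (-0.69 ± 0.15, adjusted p = 0.0246), the lipid transfer protein gene Atg2b (-0.64 ± 0.14, adjusted p = 0.0212) and the protease gene Atg4b (-0.50 ± 0.10, adjusted p = 0.0173). Over the list alone 4 rose and 4 fell, with the replicate block 5 and 4, and the list was not called (adjusted p = 0.664). Of 23 genes of ESCRT complexes and multivesicular bodies 2 rose, Vps37b (0.45 ± 0.12) and Snf8 (0.34 ± 0.09), and 2 fell, Hgs (-0.35 ± 0.07) and Vps41 (-0.33 ± 0.09), with 3 and 2 over the list alone (list adjusted p = 0.919). At day 0, 0 of these 23 passed by either adjustment (list adjusted p = 0.919). Of 24 Wnt and beta-catenin targets 2 rose by either adjustment, the Wnt inhibitor gene Apcdd1 (1.13 ± 0.17, adjusted p = 0.00326) and the transcription factor gene Lef1 (0.69 ± 0.19), with 2 higher and 2 lower with the replicate block, and the list was not called (adjusted p = 0.801). Of 22 Wnt pathway components 1 fell, the receptor gene Fzd2 (-0.79 ± 0.15, adjusted p = 0.0102), with 1 higher and 3 lower over the list alone or with the replicate block (list adjusted p = 0.664). Of 11 thyroid hormone response genes 2 fell, Dio2 (-1.47 ± 0.25, adjusted p = 0.00648) and the receptor gene Thra (-0.62 ± 0.11, adjusted p = 0.0081), with 1 higher and 3 lower over the list alone or with the replicate block (list adjusted p = 0.405). Dimmer probe sets of Atg2b (0.01 and -0.13), Fzd2 (-0.1 and -0.15) and Thra (0.02 and 0.13) changed less at day 7 and did not pass. Those of Wipi2 (0.96) and Apcdd1 (1.22 and 1.2) included ones that passed. The thyroid list mean was lower in knockdown cells in 7 of 7 pairs, with differences of -0.385, -0.121 and -0.273 at day 0 and of -0.312, -0.239, -0.089 and -0.078 at day 7. This mean leans on Dio2 (-2.4 at day 0 and -1.47 at day 7). Over the 11 genes the mean change was -0.26 at day 0 and -0.179 at day 7. The median was smaller, -0.15 and -0.053, and 4 of the 11 values were above 0 at each day. The list mean went 1 way in all 7 pairs for 7 lists: lower also for the contractile, interferon response and inflammatory genes, and higher for the mature adipocyte markers, adipogenic transcription factors and fatty acid oxidation genes.

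The day 7 count was 713, 591 and 558 without control replicate 1, 3 or 4, and 369, 377, 2885 and 461 without knockdown replicate 1, 2, 3 or 4. With the replicate block it was 2680 (1371 higher, 1309 lower; 1164 shared), without both replicate 3 arrays 2188, and in a fit of the day 7 arrays alone 333. With replicates 1 and 2 averaged it was 64 (25 higher, 39 lower; 63 shared). Of the 59 called genes that the naming rule gave for day 7, Trp53inp2 not counted, 9 kept their call then. They were Ehhadh, Popdc3, Id4, Adgrg1, Rassf3, Klhl4, Il7r, Itm2a and Kcnc2. The beta-actin difference between 3' and 5' probe sets was 3.25 ± 0.31 in day 7 controls and 3.04 ± 0.28 in knockdown cells (SD, n = 4 each; exact two-sided permutation p = 0.371, adjusted 0.556). Markers of other cell types were counted in the same way: at day 7, 0 of 12 macrophage, 0 of 10 endothelial and 0 of 10 epithelial markers passed, nor did any of these at day 0, by either adjustment. Of 11 muscle markers 1 rose at day 7 (Des, 0.61 ± 0.16) and 0 passed at day 0, and of 9 osteoblast and chondrocyte markers 0 passed at either day, with 1 lower at each with the replicate block.

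Many knockdown changes were in the same direction at both days. Of the 85 genes raised at day 0, 20 were also raised at day 7, where 2.6 would overlap for independent lists of these sizes. Of the 243 genes lowered at day 0, 95 were also lowered at day 7, against 8.7 for independent lists. In opposite directions the overlaps were 1 and 0, against 3 and 7.3. Klhl4, Meox2, Kcnc2, Il7r, Itm2a, Pde3b and Dio2 fell at both days and Popdc3, Slc4a4 and Parm1 rose at both (day 7 values of Slc4a4 and Parm1 were 2.06 ± 0.24 and 1.61 ± 0.17). The 2 contrasts share no array. A lasting difference between control and knockdown cells other than the knockdown would also give shared changes. It was not tested and cannot be told apart from an effect of the knockdown. Across the 18193 genes, which are not independent replicates, the 2 log2 fold changes correlated with Pearson r = 0.366 (jackknife SE 0.093 over arrays) and Spearman rho = 0.237.

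The knockdown effect differed between day 7 and day 0 in 4 genes. Ehhadh did not pass at day 0 (-0.12 ± 0.16) and rose at day 7, from 2.93 ± 0.21 in controls, near the bottom of the scale, to 5.16 ± 0.14 (SD, n = 4 each). The difference between the effects was 2.34 ± 0.22 (adjusted p = 0.00168). Cd274, which encodes the immune checkpoint ligand PD-L1, differed by 1.95 ± 0.27 (adjusted p = 0.047), with -0.28 ± 0.20 at day 0 and 1.66 ± 0.18 at day 7. Edem1, a gene of endoplasmic reticulum protein disposal, differed by 0.86 ± 0.12 (adjusted p = 0.047), with -0.89 ± 0.09 at day 0 and -0.03 ± 0.08 at day 7. A second, dimmer probe set of Edem1 had -0.31 at day 0 and -0.13 at day 7, and passed at neither (adjusted p = 0.203 and 0.547 over all probe sets). Gdpd2, a glycerophosphodiester phosphodiesterase gene, differed by -3.00 ± 0.42 (adjusted p = 0.047), rising at day 0 (1.98 ± 0.32) and falling at day 7 (-1.02 ± 0.27). Cd274, Edem1 and Gdpd2 lost the call under quantile normalization (1.93, 0.81 and -3.025, adjusted p = 0.0567) and with the beta-actin covariate (2.01, 0.89 and -2.98, adjusted p = 0.0519, 0.0519 and 0.0765). The next genes by p, F13a1 (2.24 ± 0.33), Mfap3l (1.41 ± 0.21), Crispld1 (-0.83 ± 0.13), Gulp1 (-0.83 ± 0.13), Ncald (-1.25 ± 0.20) and Vstm2a (-2.12 ± 0.34), had adjusted p = 0.0529. With the replicate block the adjusted p was 0.0116 for F13a1, 0.0251 for Mfap3l, 0.0406 for Crispld1, 0.0481 for Ncald and 0.0041 for Vstm2a.

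Camera called 5 lists in this contrast, none of which held with an estimated correlation. The cell cycle genes (median 0.69, adjusted p = 9.61e-08; adjusted p = 0.687 with an estimated correlation) were shifted up at day 7 relative to day 0. This rests on replicates 1 and 2 at day 0, with list mean differences of -0.843 and -0.831 against 0.137 in replicate 3 and 0.135, 0.139, 0.197 and 0.18 at day 7. Also shifted up were the genes of fatty acid and triglyceride synthesis (0.50, adjusted p = 0.00765; adjusted p = 0.772 with an estimated correlation) and those of oxidative phosphorylation (0.21, adjusted p = 0.00587; adjusted p = 0.826 with an estimated correlation). The matrix genes (-0.24, adjusted p = 8.17e-05; adjusted p = 0.687 with an estimated correlation) and the lysosomal genes (-0.19, adjusted p = 0.000226; adjusted p = 0.616 with an estimated correlation) were shifted down. Of their members 0 passed over all genes; over the list alone 1 synthesis gene was higher and 2 lysosomal genes lower. Under the replicate block 1 Wnt target and 1 contractile gene were higher, and 1 adipogenic transcription factor gene and 1 inflammatory gene lower. With the replicate block the cholesterol synthesis genes were called too (adjusted p = 0.000213, against 0.0679 without it; adjusted p = 0.853 with an estimated correlation). The mature adipocyte markers did not differ by this test (median 0.39, adjusted p = 0.225). Without day 7 control replicate 3 the calls for synthesis and oxidative phosphorylation were lost, with adjusted p = 0.0573 and 0.0835 (medians 0.33 and 0.16). With the beta-actin covariate, added after the data were seen, both were lost too (adjusted p = 0.271, median 0.22, and adjusted p = 0.343, median 0.13), and the lysosome median was -0.11. The synthesis call was also lost without the dimmest 40% of genes, with an unchanged median of 0.50 (adjusted p = 0.0517). The matrix median was -0.14 without day 0 control replicate 3 or day 7 knockdown replicate 4. The count of 4 genes was 196 with the replicate block, 1 under quantile normalization, 218 without day 0 knockdown replicate 3, 317 without day 7 knockdown replicate 3 and 0 with replicates 1 and 2 averaged. It was 17 and 8 without day 7 control replicate 3 or 4 and 2 without day 0 control replicate 3. It was 1 without day 0 control replicate 1, day 0 knockdown replicate 1 or 2, day 7 control replicate 1 or 2, or day 7 knockdown replicate 1, 2 or 4. For this contrast 2403 genes had an unadjusted limma p under 0.05.

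Differentiation of control cells changed 4162 genes, 1842 higher and 2320 lower at day 7, 637 and 612 of them by at least 2-fold. The 10 largest increases among genes named by the rule were led by Fam107a (7.00 ± 0.58). They also held Lcn2 (lipocalin 2, 6.16 ± 0.55), the adiponectin gene Adipoq (5.87 ± 1.05), Orm1 (5.65 ± 0.43), the resistin gene Retn (5.56 ± 0.65) and Retnla (5.48 ± 0.53). The others were the chemokine gene Cxcl13 (5.74 ± 0.37), Wfdc21 (5.70 ± 0.37), the lipid droplet lectin gene Lgals12 (5.60 ± 0.60) and the carbonic anhydrase gene Car3 (5.51 ± 0.57). Adjusted p for these lay between 2.54e-06 and 0.00161. The largest decreases were in Mlana (-5.65) and the microfibril protein gene Mfap4 (-5.59 ± 0.23); they also held the collagenase gene Mmp13 (-4.16 ± 0.58), Fbln7 (-3.85 ± 0.53), the hyaluronidase gene Cemip (-3.82 ± 0.31) and Mmp11 (-3.77 ± 0.39). Rab27a (-3.99), the prostaglandin synthase gene Ptgds (-3.93), the chemokine gene Ccl8 (-3.85) and Dmp1 (-3.77) also fell; Ccl8 had adjusted p = 0.0992 with replicates 1 and 2 averaged.

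Of 24 mature adipocyte markers 16 rose and 0 fell, with a median of 2.18 (17 over the list alone; adjusted p = 1.59e-09; adjusted p = 0.611 with an estimated correlation). Of 18 adipogenic transcription factor genes 9 rose by either adjustment (median 0.45, adjusted p = 0.00375; adjusted p = 0.687 with an estimated correlation). Of 18 fatty acid oxidation genes 12 rose by either adjustment (median 0.56, adjusted p = 5.17e-06; adjusted p = 0.611 with an estimated correlation). Of 14 lipolysis genes 8 rose and 1 fell, with 10 and 1 over the list alone (median 1.15, adjusted p = 1.85e-05; adjusted p = 0.611 with an estimated correlation). All 27 genes of S phase and mitosis rose by either adjustment, by a median of 2.04 (adjusted p = 9.76e-26; adjusted p = 0.55 with an estimated correlation). Of 21 oxidative phosphorylation genes 7 rose, with 13 over the list alone (median 0.30, adjusted p = 8.92e-06; adjusted p = 0.707 with an estimated correlation). Of 24 interferon response genes 17 fell, with 21 over the list alone (median -2.01, adjusted p = 1.54e-08; adjusted p = 0.687 with an estimated correlation). Of 22 lysosomal genes 16 fell, with 18 over the list alone (median -0.42, adjusted p = 4.44e-09; adjusted p = 0.55 with an estimated correlation). Of 24 matrix genes 13 fell, with 18 over the list alone (median -0.38, adjusted p = 1.61e-05; adjusted p = 0.687 with an estimated correlation). Of 17 cholesterol synthesis genes 9 fell, with 11 over the list alone (median -0.86, adjusted p = 1.5e-05; adjusted p = 0.707 with an estimated correlation). Of 19 preadipocyte genes 8 fell, with 11 over the list alone (median -0.48, adjusted p = 0.000235; adjusted p = 0.55 with an estimated correlation). Of 33 autophagy genes 10 fell, with 11 over the list alone (median -0.23, adjusted p = 0.00555; adjusted p = 0.55 with an estimated correlation).

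In knockdown cells differentiation changed 6506 genes, 3455 higher and 3051 lower, 1258 and 961 of them by at least 2-fold. The largest increases were in Lcn2 (8.47 ± 0.55), Retnla (7.82 ± 0.53), Map7d2 (6.62 ± 0.59), the lipid droplet gene Cidec (6.62 ± 0.74) and the lipase inhibitor gene G0s2 (6.18 ± 0.66). The largest decreases were in Fbln7 (-5.62 ± 0.53), Mfap4 (-5.18 ± 0.23), Ggt5 (-4.93 ± 0.62), the apolipoprotein gene Apod (-4.77 ± 0.44) and Mlana (-4.46 ± 0.27). Adjusted p for these 10 genes lay between 6.83e-08 and 5.72e-05. Of 4162 genes changed in control cells, 3472 changed in the same direction in knockdown cells; 2747 of the 4162 (66%) had the larger absolute change there, and the difference itself is the contrast described above. In knockdown cells 17 of 24 mature adipocyte markers rose (18 over the list alone), 17 of 21 oxidative phosphorylation genes rose (18 over the list alone) and 20 of 24 matrix genes fell (21 over the list alone). Averaging replicates 1 and 2 left 1584 genes in control cells and 4098 in knockdown cells.

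The day 7 knockdown effect correlated in part with the differentiation change of control cells. Across genes, which are not independent replicates, the 2 log2 fold changes correlated with Pearson r = 0.286 (jackknife SE 0.09), Spearman rho = 0.251 and a covariance of 0.0645. Both contrasts use the day 7 controls with opposite sign, and unchanged groups simulated against those controls gave r = -0.464 and a covariance of -0.0201, a difference in covariance of 0.0846. With the day 7 controls split between the contrasts, r lay between 0.209 and 0.516 over 6 splits. With each replicate number kept to 1 of the contrasts, in control and knockdown arrays alike, r lay between 0.184 and 0.444 over 6 splits, a test chosen after the result was seen. Of the genes called in both contrasts, 179 were raised and 262 lowered in both, 46 were raised by knockdown and lowered by differentiation, and 41 the reverse. Slc6a2 (3.06 in differentiation, -2.81 with knockdown), Tnfsf11 (2.99 and -2.71), Cxcl13 (5.74 and -1.71) and Cebpd (0.96 and -0.90) went in opposite directions. So did the cholesterol synthesis list, called as lowered in differentiation and as raised with knockdown (medians -0.86 and 0.34; adjusted p = 0.707 and adjusted p = 0.772 with an estimated correlation).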

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

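The 3 tests of the first pattern below, the averaging of replicates 1 and 2 and the covariate for RNA quality were chosen only after the result was seen. The effect of knockdown differed between day 7 and day 0, by the test of the difference itself, for Ehhadh (2.34), Cd274 (1.95), Edem1 (0.86) and Gdpd2 (-3). A second, dimmer probe set of Edem1 had -0.31 at day 0 and -0.13 at day 7, and passed at neither. By camera the effect differed for 5 lists, with median differences of 0.688 (S phase and mitosis), 0.497 (fatty acid and triglyceride synthesis), 0.205 (oxidative phosphorylation), -0.238 (matrix) and -0.186 (lysosome). These 5 calls are lost with an estimated correlation (adjusted p = 0.687, 0.772, 0.826, 0.687 and 0.616 in this order). The first rests on day 0 replicates 1 and 2 (list mean differences of -0.843 and -0.831), as day 0 replicate 3 had 0.137. Of 100 drawn splits within each day, 2 gave as many as the 4 genes of the real one, itself included, and the other gave 35, several times the real count, which points to a structure of the samples; its cause was not tested.

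Day 7 replicate 3 stood apart in many of the named genes and lists, in both genotypes. Among groups of 4, 31 of 230 had 1 array far from the others, where chance gives about 1 in 20, or 11.5. In knockdown cells, replicate 3 was lower in Trim29 (7.56), Cidec (8.89), G0s2 (10.63), Lef1 (10.85), Hadha (9.25), Cyp51 (10.96) and in the means of fatty acid and triglyceride synthesis (9.95), lipolysis (9.06) and cholesterol synthesis genes (9.57). It was higher in Meox2 (4.71, the others 2.53 to 2.55), Timp3 (8.14), Vstm2a (12.28), Atg2b (7.84), Dcn (10.91) and the mean of inflammatory genes (10.05, the others 8.28 to 8.43). In controls, replicate 3 was higher in Lcn2 (13.64, the others 11.2 to 11.26), Mmp13 (8.05), Ccl8 (10.55), Cemip (4.95), Vstm2a (11.87) and the means of inflammatory genes (10.34, the others 8.5 to 8.71) and endothelial markers (3.61), and lower in Fbln7 (3.04) and the mean of Wnt pathway components (8.84). Other arrays far from their group were control replicate 4 in Slc22a22 (7.95), Dgat2 (7.86) and the brown and beige list (4.31), control replicate 2 in Rab27a (4.32), and knockdown replicate 2 in Kcnc2 (5.07) and replicate 4 in Pde3b (8.65) and Vps37b (7.28).

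The first pattern is that the day 7 knockdown effect correlated with the differentiation change of control cells, with 46 and 41 genes called in opposite directions. Sharing the day 7 controls pushes the correlation down, and with these controls split its mean over 6 splits was 0.341, above 0 in each. Arrays of the same number also deviate together. With each number kept to 1 contrast, the lower correlation of the 2 splits that leave replicates 1 and 2 together was 0.184. This lies just above the bound of 2 SE of 0.09. That SE belongs to the correlation over all arrays and not to a split with fewer arrays, so the bound does not decide on that cause. A difference between cultures in how far they differentiated stays open: the slope was above 0 for 4 of 4 replicate numbers (0.151, 0.131, 0.164 and 0.349), and the exact sign-flip p = 0.125 is the smallest that 4 numbers allow. An effect of the knockdown cannot be told apart from such a difference.

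The second pattern is the lower level of interferon response genes in knockdown cells. The difference was below 0 for 7 of 7 replicate numbers (mean -0.78, from -1.16 to -0.54), with an exact sign-flip p = 0.0156, the smallest that 7 allow and under the bound written beforehand. Day 7 replicates 1 and 2 may lie too close together to count separately (SD of their difference 0.111 in controls and 0.179 in knockdown cells). With them averaged, 6 of 6 numbers were below 0 (exact sign-flip p = 0.0312). At day 0 replicates 1 and 2 lie less close (0.246 and 0.224). With these averaged too, 5 numbers give an exact sign-flip p = 0.0625, the smallest possible. Both ways of averaging were chosen after the values were seen, and these p are not adjusted over the lists. Only if day 0 replicates 1 and 2 count as separate do the values argue against a chance difference between cultures in interferon level. The labels do not settle this, so such a difference is not excluded. A lasting difference between control and knockdown cells, from the virus that carries the knockdown or from how the cells were derived, was not tested and stays open beside an effect of the knockdown.

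The third pattern is the day 0 effect, beside a beta-actin measure of RNA quality that moved with the groups. With the beta-actin difference as a covariate, the 328 genes had a median ratio of adjusted to unadjusted change of 1.03 (quartiles 0.89 to 1.16) and 100% kept their direction. The day 0 groups do not overlap in this difference (3.32 to 3.76 in controls, 2.74 to 3.23 in knockdown cells). The adjustment therefore rests on variation within groups and cannot separate knockdown from RNA quality at day 0. List medians moved more, from 0.36 to 1.38 for mature adipocyte markers, from -0.69 to -1.92 for interferon response genes and from -0.39 to -0.70 for contractile genes. Of the 328 genes 193 stayed past the threshold, while their median SE rose from 0.165 to 0.2. The 10 splits of 6 samples are too few for a share under 0.05; the real split gave 328 genes, 1 of 10 gave as many, and the highest other gave 0.

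At day 7, 1 of 35 splits of the 8 samples gave as many as 1197 genes, the real one. The highest other, 1099, exchanged control replicate 2 with knockdown replicate 3. This share is under 0.05 only if every array counts as independent, and arrays of the same number deviate together. Of the 8 splits that part all 4 pairs 1 gave as many, and the highest other of these gave 1; 8 are too few for such a share, so chance is not excluded. For differentiation, 1 of 35 splits gave as many in control cells (4162, highest other 1956) and 1 of 35 in knockdown cells (6506, highest other 5378, with knockdown day 7 replicate 3 placed among the day 0 arrays). With each array counted as a sample, this argues against chance, and averaging replicates 1 and 2 left 1584 and 4098 genes.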

How the results depend on the processing

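Averaging replicates 1 and 2, leaving out both day 7 replicate 3 arrays, the covariate for RNA quality and the block with an estimated correlation were chosen only after the data were seen. Counts are given for knockdown at day 0, knockdown at day 7, the difference between days, and differentiation in control and knockdown cells, in this order where several are named. Averaging gave 24, 64, 0, 1584 and 4098, with fewer samples, and leaving out both replicate 3 arrays 690, 2188 and 266 for the first 3. The covariate gave 590 and 2804 for the first 2, and 4 genes for the third, 1 of them (Ehhadh) shared. The replicate block gave 844, 2680 and 196, of which 302, 1164 and 4 were shared with the main fit. It ended no call of a named gene, or of a list in the knockdown contrasts, but those given beside the results. Array weights gave 1752, 4488, 1663 and 7110 for the first 4. A change of at least 2-fold left 146, 245, 1249 and 2219, without the difference between days. Testing every probe set gave 1260 (791 higher, 469 lower, against most genes lower by 1 probe set per gene), 83, 7871 and 14099, without day 7. Without the dimmest 40% of genes, so with fewer tests, the first 3 were 498, 1831 and 57. Fits of the compared groups alone gave 207 and 333 for knockdown. Arrays shifted to 1 median gave 513 at day 0. The difference between days had 8 genes with a variance trend, 12 with the probe set of largest interquartile range and 1 under quantile normalization. Where no reason is named, the cause was not tested.

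Leaving out 1 array at a time gave 101 to 631, 369 to 2885, 1 to 317, 3009 to 4543 and 5462 to 6894 genes, and -1.36 to -1.06 and -1.66 to -1.51 for Trp53inp2 at day 0 and day 7. Correlations ran from 0.316 to 0.413 between the knockdown effects and from 0.21 to 0.313 with differentiation. The Trp53inp2 decrease at day 0 was -0.48 (adjusted p = 0.105) with the mean over its probe sets, where the dim probe set did not fall, and -1.06 (adjusted p = 0.165) with replicates 1 and 2 averaged. With the probe set of largest interquartile range, another probe set of the gene, Wipi2 at day 0 turned to -0.155 (adjusted p = 0.687), and at day 7 Wnt5a to 0.139 (0.761), Pik3ca to 0.077 (0.926) and Cblb to 0.052 (0.885). Of the 59 called genes that the naming rule gave for day 7, 31 lost the call without some array and 50 with replicates 1 and 2 averaged. At day 0 it was 9 and 18 of 28, with Trp53inp2 not counted at either day. Dim genes are limited by the background of the arrays, for which no detection call was given.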

Other observations

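Listed preadipocyte markers and genes that oppose fat cell formation changed in both directions with knockdown at day 7. Of 19 such genes 2 rose, the zinc finger factor genes Gata3 (0.92 ± 0.18, adjusted p = 0.0146) and Gata2 (0.56 ± 0.15). A dimmer probe set of Gata2 had 0.06 (adjusted p = 0.91 over all probe sets). Those that fell were 2, Wnt5a (-0.61 ± 0.11, adjusted p = 0.00937) and the growth factor receptor gene Pdgfra (-0.49 ± 0.13, adjusted p = 0.0436). Adjusted over the list alone 2 rose and 5 fell, with the replicate block 3 and 4, and the list was not called (adjusted p = 0.133). At day 0, 0 of 19 passed by either adjustment and 1 was lower with the replicate block (list adjusted p = 0.591). Of 15 genes of insulin signalling and glucose uptake, the adaptor gene Irs2 rose (0.76 ± 0.17, adjusted p = 0.0256) and 3 fell, Pde3b, Pik3ca (-0.36 ± 0.08, adjusted p = 0.0209) and the ubiquitin ligase gene Cblb (-0.29 ± 0.07, adjusted p = 0.0271). By the probe set of largest interquartile range Wnt5a (0.139), Pik3ca (0.077) and Cblb (0.052) had the opposite sign and did not pass. Over the list alone 2 rose and 4 fell, with the replicate block 3 and 3 (list adjusted p = 0.802), and at day 0 1 fell, Pde3b, by either adjustment (list adjusted p = 0.984). Of 17 brown and beige adipocyte markers 1 rose, Cited1 (0.50 ± 0.14), and 1 fell, Dio2, by either adjustment, with 2 and 2 with the replicate block (list adjusted p = 0.878). At day 0, Dio2 and Fgf21 fell by either adjustment, and 1 with the replicate block (list adjusted p = 0.297). That list's median of 0 at day 7 and mean of -0.081 stood beside a test direction of up.

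Of 18 p53 target genes 2 rose at day 7 by either adjustment, Phlda3 (0.54 ± 0.09, adjusted p = 0.00633) and Ei24 (0.34 ± 0.08, adjusted p = 0.0359), and 0 passed at day 0 (list adjusted p = 0.878 and 0.922); with the replicate block 2 were also lower at day 7 and 1 at day 0. Of 19 genes of the unfolded protein and integrated stress responses 1 fell at day 7, the lipoprotein receptor gene Vldlr (-0.56 ± 0.14, adjusted p = 0.0379), and 1 at day 0, by either adjustment (list adjusted p = 0.725 and 0.609). Of 11 muscle markers 1 rose at day 7, the desmin gene Des (0.61 ± 0.16, adjusted p = 0.044; list adjusted p = 0.331), and 0 passed at day 0. Of 19 inflammatory and acute phase genes 0 passed at either day (list adjusted p = 0.957 at day 0 and 0.475 at day 7). Under the replicate block 1 was higher and 2 lower at day 0, and 4 lower at day 7. The list mean was lower in knockdown cells in 7 of 7 pairs, with differences of -0.203, -0.315 and -0.189 at day 0 and of -0.165, -0.09, -0.294 and -0.436 at day 7. Of 9 osteoblast and chondrocyte markers 0 passed at either day (list adjusted p = 0.248 and 0.378), and 1 was lower at each with the replicate block. Sox9 had -0.78 ± 0.26 at day 7 (adjusted p = 0.0917).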
